A study of Mus musculus and Homo sapiens with 30 samples.

How the data were processed

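Total RNA from 2 cell lines was measured on Affymetrix oligonucleotide arrays. M-O7e is a human megakaryoblastic line, and PG13 is a mouse fibroblast line used to package retroviral vectors. Each line had been transduced with a retroviral vector carrying Smad7 or with the vector alone, and the transduced cells were sorted to an estimated purity that the labels give in the same words for every group. Each line and vector had 3 replicates. RNA from M-O7e was hybridised to the chips HG-U133A and HG-U133B (12 arrays), and RNA from PG13 to MG_U74Av2, MG_U74Bv2 and MG_U74Cv2 (18 arrays), which makes 30 arrays. The labels count 4 samples behind the 30 arrays and give every replicate of a group the same RNA concentration. Nothing in them says that replicates came from separate cultures, so p-values measure only the spread between these replicates, which may be technical. Replicates were taken from the titles, and the arrays of one replicate number on the chips of a line were stacked.

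The deposited values were intensity signals on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes; the version was not given in the sources used here. The trimmed mean of the deposited signals lay close to 1500 on each of the 30 arrays. No detection call was used, and no probe-level values were analysed here.

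Each array was rescaled to a common trimmed mean (2% removed at each end, control probe sets left out) within its chip, and log2(signal + 16) was taken, so that fold changes of dim probe sets are understated. A probe set was tested where its signal lay above the array median in at least 3 of the 6 replicates of the line. The 100 probe sets printed on both human chips were used once. This left 23286 of 44792 probe sets for M-O7e and 18989 of 36701 for PG13. Smad7 vector was compared with vector alone in each line with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets of the line and an adjusted p threshold of 0.05. All p-values were two-sided. The difference of the effect between the lines was tested in 1 limma fit over the replicates of both lines, on the brightest probe set of each gene with the same symbol in both. This fit used 1 residual variance per gene for both lines. The precision of every value is limited by the number of arrays. Single measures of array quality were compared by exact permutation tests, which cannot go below 0.1 with 3 replicates against 3.

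Gene symbols came from the platform annotation supplied with the data, which can be old. On HG-U133A 19065 probe sets had 1 symbol, 1043 several and 2107 none. The same counts were 15426, 554 and 6597 on HG-U133B, then 10833, 396 and 1193 on MG_U74Av2, then 10581, 178 and 1652 on MG_U74Bv2, and 7717, 150 and 4001 on MG_U74Cv2. Only probe sets with 1 symbol were named. The remaining ones are unnamed here.

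The groups, tests, alternatives, named-gene rule and 24 gene lists were fixed before the data were examined. The rule named every SMAD gene, the 10 genes with the largest rise and the 10 with the largest fall among called probe sets whose replicates did not overlap between groups, each gene by its brightest called probe set, up to 4 called members of each list or else the 2 members with the smallest p, and the 10 genes with the smallest p for the difference between the lines. Gene lists were tested with camera in limma (preset correlation 0.01) on the brightest probe set of each gene, where at least 5 members were measured, with adjustment over the lists of the line. Camera with an estimated correlation and fry were run beside it.

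Array runs were taken from the scan times the array records give, a new run of a chip starting after a gap of over 60 minutes. In M-O7e, 1 run held the 3 Smad7 replicates and vector replicate 1, and the other held vector replicates 2 and 3. In PG13, 1 run held Smad7 replicates 1 and 2, and the other held Smad7 replicate 3 and the 3 vector replicates. The division was the same on every chip. Within each line only 1 run held both groups, so a fit with the run as a block gives the value within that run.

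The steps were tested on simulated data drawn around the real means and spreads, with 200 changed probe sets, one part by 2-fold and the other by 4-fold. For M-O7e (23286 probe sets), 13% of 2-fold and 53% of 4-fold changes were recovered, and 7 of 73 calls were unchanged probe sets. For PG13 (18989 probe sets), 12% and 61% were recovered, and 8 of 81 calls were unchanged. With nothing changed, 0 probe sets were called in M-O7e and 1 in PG13. A list shifted by 0.5 on the log2 scale was called in both lines with no other list. The noise was drawn independently for each probe set, so the list test was not tried on correlated genes. The shift was also larger than the median of any list called in the real data. For the difference between lines (6986 genes), 78% of 4-fold differences were recovered, and 11 of 167 calls were unchanged genes.

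The alternatives were pseudocounts of 1 and 64, quantile and median scaling, the values as deposited, no filter and a stricter one, each chip fitted on its own, the first chip alone, eBayes without the trend, the replicate number as a block, the array run as a block, the mean of a gene's probe sets, the other list tests, and leaving out each replicate in turn. The ribosomal RNA signal of the arrays as a covariate was added after seeing the data. Figures were drawn with matplotlib 3.10.9.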

Results

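The series asks what Smad7, an inhibitory member of the SMAD family that blocks signalling by receptors of the TGF-beta family, does in a blood cell line and in a cell line of another origin. Expression was measured in M-O7e, a human megakaryoblastic line that depends on growth factors, and in PG13, a mouse fibroblast line that packages retroviral vectors. Cells carrying the Smad7 vector were compared with cells carrying the vector alone, with 3 replicates of each in each line and 30 arrays in all. Levels are MAS5 signals rescaled to a common trimmed mean, given as mean ± SD with n = 3 per group.

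SMAD7 itself was read first, as a check of the labels. In M-O7e its signal was 917.8 ± 146 with the Smad7 vector and 236.5 ± 115 with vector alone, and all 3 Smad7 replicates (1043, 757.5 and 953 units) lay above the 3 vector replicates (311, 104 and 294 units). The log2 fold change was 2.01 (SE 0.64, 4.02-fold, 95% interval 0.54 to 3.48), with a limma adjusted p of 0.223 and an exact permutation p of 0.1, the smallest that 3 against 3 allows. Within the shared array run it was 1.5 (SE 0.90). In PG13 the 1 Smad7 probe set read 2426 ± 268 with the Smad7 vector and 2432 ± 554 with vector alone, a log2 fold change of 0.02 (SE 0.24, 95% interval -0.52 to 0.56, limma adjusted p = 0.997, exact permutation p = 1), and 0.01 (SE 0.36) within the shared run. Whether the probe set of either line can read the Smad7 sequence of the vector is unknown. The PG13 value therefore neither checks nor contradicts the labels, and the M-O7e rise, which did not pass, is a limited check of them. No tested SMAD gene, SMAD7 included, passed the test in either line. By brightest probe set, the log2 fold changes in M-O7e were -0.12 for SMAD1, 0.25 for SMAD2, -0.08 for SMAD3, -0.26 for SMAD4, -0.20 for SMAD5 and 0.41 for SMAD6. In PG13 they were 0.32 for Smad1, 0.21 for Smad2, 0.04 for Smad3, 0.50 for Smad4, 0.27 for Smad5 and 0.17 for Smad6.

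**Figure D1:**
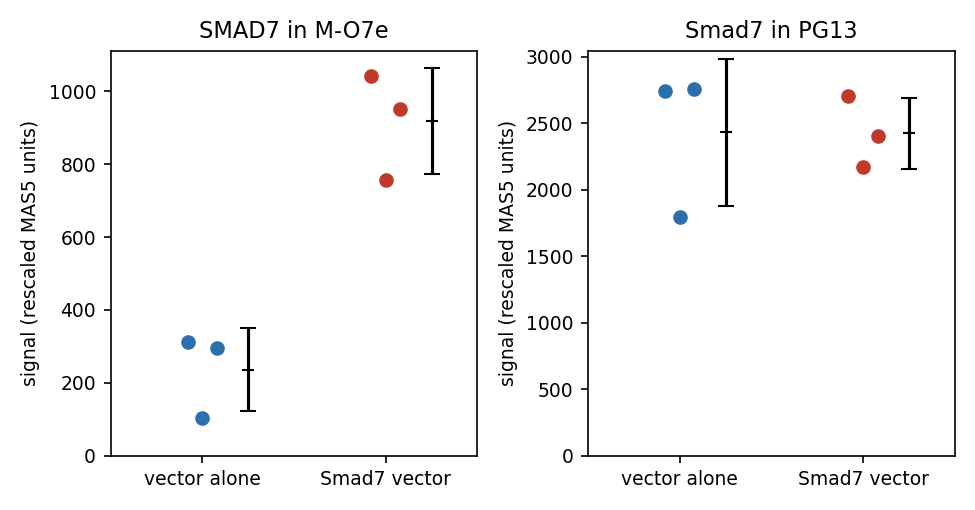
Signal of the SMAD7 probe set in M-O7e and the Smad7 probe set in PG13 (rescaled MAS5 units, each replicate a point, bars the mean ± SD, n = 3). The M-O7e groups averaged 917.8 and 236.5 units, and the PG13 groups 2426 and 2432 units.

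In M-O7e the receptor tyrosine kinase KIT, which binds stem cell factor, rose 3.31-fold with Smad7, from 9993 ± 1551 to 32848 ± 1006 units (n = 3, log2 fold change 1.73, SE 0.14, limma adjusted p = 0.0124). By the brightest called probe set of each gene, the largest named rises were GNG11, a G protein gamma subunit, at 3.13 on the log2 scale (SE 0.47, 8.73-fold, limma adjusted p = 0.0392), and AHNAK, a very large scaffold protein, at 3.11 (SE 0.42). FAM241A (3.01), PPP1R12C, a myosin phosphatase subunit (2.56), the ubiquitin-conjugating enzyme UBE2E2 (2.14), NUTM1 (2.13), the regulator of G protein signalling RGS16 (2.00), TCAM1P (1.91) and the lipid phosphatase PLPP4 (1.81) also rose. The largest named fall was ENSA, which encodes an inhibitor of protein phosphatase PP2A, at -3.59 (SE 0.46, from 7356 ± 1011 to 704 ± 517 units, limma adjusted p = 0.0213). SLC39A3, a zinc transporter, fell by 3.08, SLC35F3 by 2.78, LOC400499 by 2.59, CD70, the ligand of CD27, by 2.54. RASSF4 fell by 2.37. DOCK5, an exchange factor for Rac, fell by 2.30, XRRA1 by 2.29, BTBD10 by 2.26 and NUCKS1 by 2.17. By a dimmer called probe set UNC13D fell by 2.94 and ARHGDIA by 2.67.

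**Figure D2:**
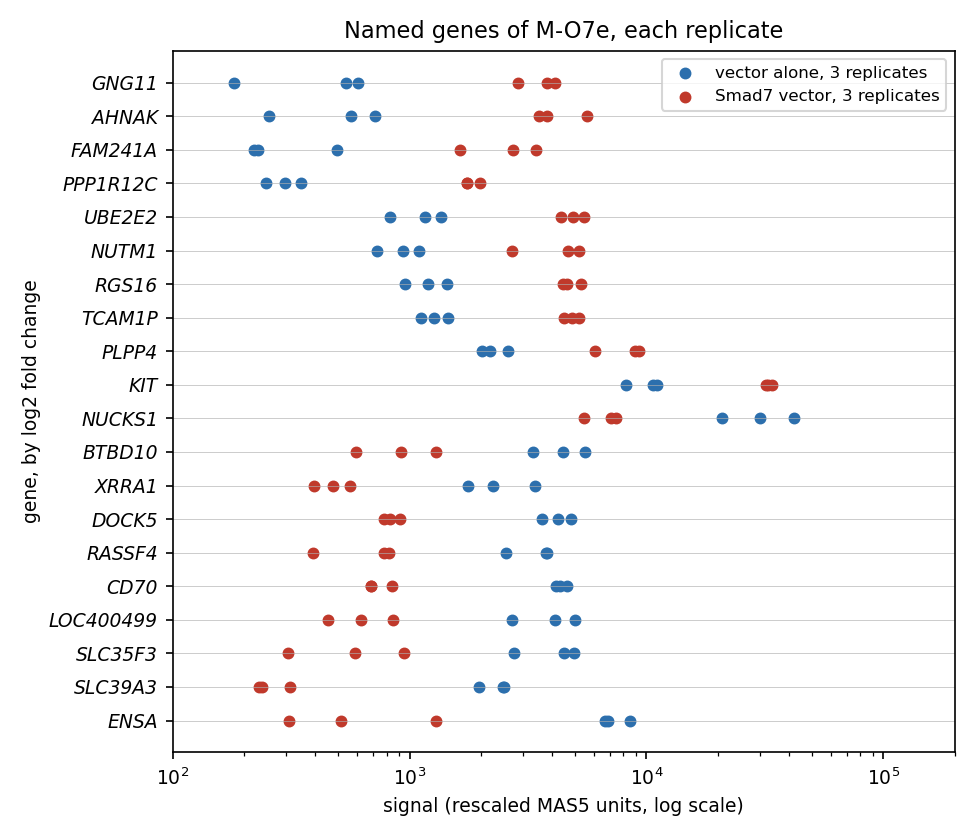
Signal of the 20 named genes of M-O7e with the largest rises and falls by the brightest called probe set of each gene (horizontal log axis, rescaled MAS5 units, each replicate a point). In KIT the Smad7 replicates averaged 32848 units and the vector replicates 9993 units. The groups do not overlap in any gene shown, because the rule named only such probe sets.

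These genes were part of 128 M-O7e probe sets that passed the test among 23286, of which 43 were higher and 85 lower with Smad7. Of these, 103 changed at least 2-fold, and 106 carried 1 symbol, naming 93 genes (32 higher, 61 lower). The 100 probe sets printed on both human chips had a median log2 fold change of 0.05 on HG-U133A and -0.23 on HG-U133B (Pearson r 0.55). The excess of falls may therefore in part be an offset between the chips, which was not tested. HG-U133A alone gave 420 calls, of which 40.5% were higher. The groups did not overlap in 4657 of the tested probe sets, where chance gives 10% of them, and 3200 had an unadjusted p under 0.05, where chance gives 1164. Median scaling moved the median log2 fold change of all probe sets from 0.04 to -0.09 and left 35 calls, of which 20% rather than 33.6% were higher. With the ribosomal RNA signal as a covariate the balance turned, with 46 of 60 calls higher and 14 lower. All 128 kept their sign and an unadjusted p under 0.05 (limma), and their median absolute log2 fold change was 1.35 (median SE 0.196) against 1.39 (median SE 0.172) without it. With the array run as a block 2 calls were left, although all 128 log2 fold changes kept their sign (KIT 1.57, GNG11 2.68, ENSA -3.81, CD70 -2.52 and DOCK5 -2.31 within the shared run). Over all settings the limma adjusted p of KIT ranged from 5.75e-05 to 0.107. The count rested on single replicates: it was 5, 4 and 33 without Smad7 replicates 1, 2 and 3, and 6, 439 and 2 without vector replicates 1, 2 and 3. Of the 27 named genes that passed, 13 had several probe sets, and in 5 of them (ENSA, NUCKS1, NCAM1, RASSF4 and TPM4) these disagreed in sign. The brightest ENSA probe set gave -0.13 (limma adjusted p = 0.724), a further GNG11 probe set 0.24 (limma adjusted p = 0.862) and the brightest SLC39A3 probe set -0.59 (limma adjusted p = 0.339). The brightest PPP1R12C probe set gave 0.57 (limma adjusted p = 0.304), and the 7 further NUCKS1 probe sets, none of which passed, lay between -0.88 and 0.18, while all 3 probe sets of DOCK5 passed with falls.

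Of the 24 gene lists, 3 were higher with Smad7 in M-O7e. With an estimated correlation none of them passed (adjusted p = 0.335 for each). The estimates were -0.008 for interferon response genes, -0.020 for TGF-beta target genes and 0.014 for erythroid markers. They lay near or below the preset 0.01, which argues against a high correlation as the reason for the loss. List members were counted by the brightest probe set of each gene, and by a dimmer one RHAG, CD44, ETV6, CDK6 and CALR also passed. Among 37 measured interferon response genes, HLA-B and HLA-C, which present peptides to T cells, rose by 1.38 (SE 0.15) and 1.15 (SE 0.15) on the log2 scale, and 35 did not pass. Adjusted over the list alone, 5 were higher, the others being HLA-E (0.65), B2M, the light chain of class I molecules (0.59), and PSMB8, an immunoproteasome subunit (1.99). The HLA values come from probe sets with the shared-sequence suffix, and the HLA-E probe set without it gave -0.05 (SE 0.24), so these need not be separate rises. Among 26 measured TGF-beta target genes 0 passed with limma over all probe sets (7 had an unadjusted p under 0.05) and 2 were higher adjusted over the list alone, ID2 at 1.58 (SE 0.28) and KLF10 at 0.93 (SE 0.22), both transcription regulators. Among 23 erythroid markers 0 passed with limma (8 at an unadjusted p under 0.05) and 3 were higher adjusted over the list alone, namely SLC25A37, an importer of iron into mitochondria (1.10), RHAG (0.75) and the transferrin receptor TFRC (0.63). The list medians were 0.31 for interferon response genes (25 of 37 positive), 0.37 for TGF-beta target genes (18 of 26) and 0.26 for erythroid markers (17 of 23), each with a camera adjusted p of 0.0216. Within the shared array run the adjusted p was 0.107 for interferon response genes, 0.0479 for TGF-beta target genes and 0.0467 for erythroid markers. Without a filter the 3 were 0.0637, 0.0593 and 0.369, with the mean of a gene's probe sets the last 2 were 0.0696 and 0.194, and without Smad7 replicate 1 the erythroid list had an adjusted p of 0.137. With the ribosomal RNA signal as a covariate the adjusted p was 0.0354 for interferon response genes, 0.219 for TGF-beta target genes and 0.177 for erythroid markers. Over all settings of camera the adjusted p ranged from 0.00556 to 0.335 for interferon response genes, 0.00131 to 0.335 for TGF-beta target genes and 0.00556 to 0.369 for erythroid markers.

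The other M-O7e lists did not pass as lists, though 6 of their members did as single genes. MS4A3, a membrane protein of myeloid cells, fell by 1.70 (SE 0.19) and the other 15 measured myeloid markers did not pass, with 3 higher and 1 lower adjusted over the list alone (FCER1G at 1.07 and ANPEP at 1.40 among the higher). PRF1, the pore-forming protein perforin, rose by 1.31 (SE 0.15) among 14 lymphoid markers, of which 1 was higher and 5 lower adjusted over the list alone (ZAP70 -1.20, LEF1 -1.52). KIT was the 1 of 24 stem and progenitor genes that passed, with 3 higher and 3 lower adjusted over the list alone (SPINK2 1.98, TIE1 -1.33). The adhesion receptor NCAM1 fell by 1.28 (SE 0.13) among 24 integrins and adhesion receptors (1 higher and 3 lower adjusted over the list alone), the tropomyosin TPM4 by 0.93 (SE 0.13) among 31 smooth muscle and actin cytoskeleton genes (3 higher, 3 lower), and the fatty acid desaturase FADS2 by 1.10 (SE 0.17) among 26 cholesterol synthesis genes (1 higher, 2 lower). The camera adjusted p was 0.484 for the myeloid list, 0.572 for the lymphoid, 0.619 for the stem and progenitor, 0.484 for the adhesion, 0.711 for the actin and 0.569 for the cholesterol list. Camera gave the direction of the lymphoid list as down, while its median (0.01) and mean (0.06) lay above 0.

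In 15 further M-O7e lists 0 members passed over all probe sets with limma by their brightest probe set, and 74 of their 468 measured members (a gene in several lists counted in each) had an unadjusted p under 0.05. Among 32 TGF-beta family ligands, receptors and Smads, the coreceptor TGFBR3 (2.18, SE 0.37, limma adjusted p = 0.0602) and the ligand TGFB1 (-0.93, SE 0.19, limma adjusted p = 0.0892) were the 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.619). Among 39 apoptosis genes 4 were higher and 1 lower adjusted over the list alone, including BMF (2.76), TP73 (3.25) and BAX (-1.62), with a camera adjusted p of 0.650. Immediate early genes had the largest median of the 24 M-O7e lists (0.40 over 28 genes, EGR1 1.37, DUSP1 0.83, 0 adjusted over the list alone, camera adjusted p = 0.119). NF-kappa B target genes had 3 higher (TNF 2.83, TNFAIP3 0.51), cell cycle genes 1 higher and 2 lower (CKS2 0.70, TOP2A -0.65), Wnt signalling genes 2 higher and 1 lower (RSPO3 1.74), adipocyte genes 1 and 1 (DGAT2 1.57, FASN -0.69), heat shock genes 1 higher (HSPB1 0.85) and glycolysis and hypoxia genes 1 lower (PKM -0.88), each adjusted over the list alone. The camera adjusted p values of these lists were 0.484, 0.484, 0.322, 0.619, 0.518 and 0.732 in that order. Megakaryocyte and platelet markers (25 genes, median 0.12, PTGS1 0.43, FLI1 -0.80, camera adjusted p = 0.619) had 0 adjusted over the list alone. So did fibroblast and extracellular matrix genes (median 0.15, PLOD1 0.92), osteoblast and chondrocyte genes (0.20, SOX5 0.59), ribosomal protein genes (0.08, RPS9 -0.62) and endoplasmic reticulum stress genes (-0.06, CEBPG -0.72), each with a camera adjusted p of 0.569, and oxidative phosphorylation genes (-0.02, UQCRC1 -0.34) with 0.484.

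**Figure D3:**
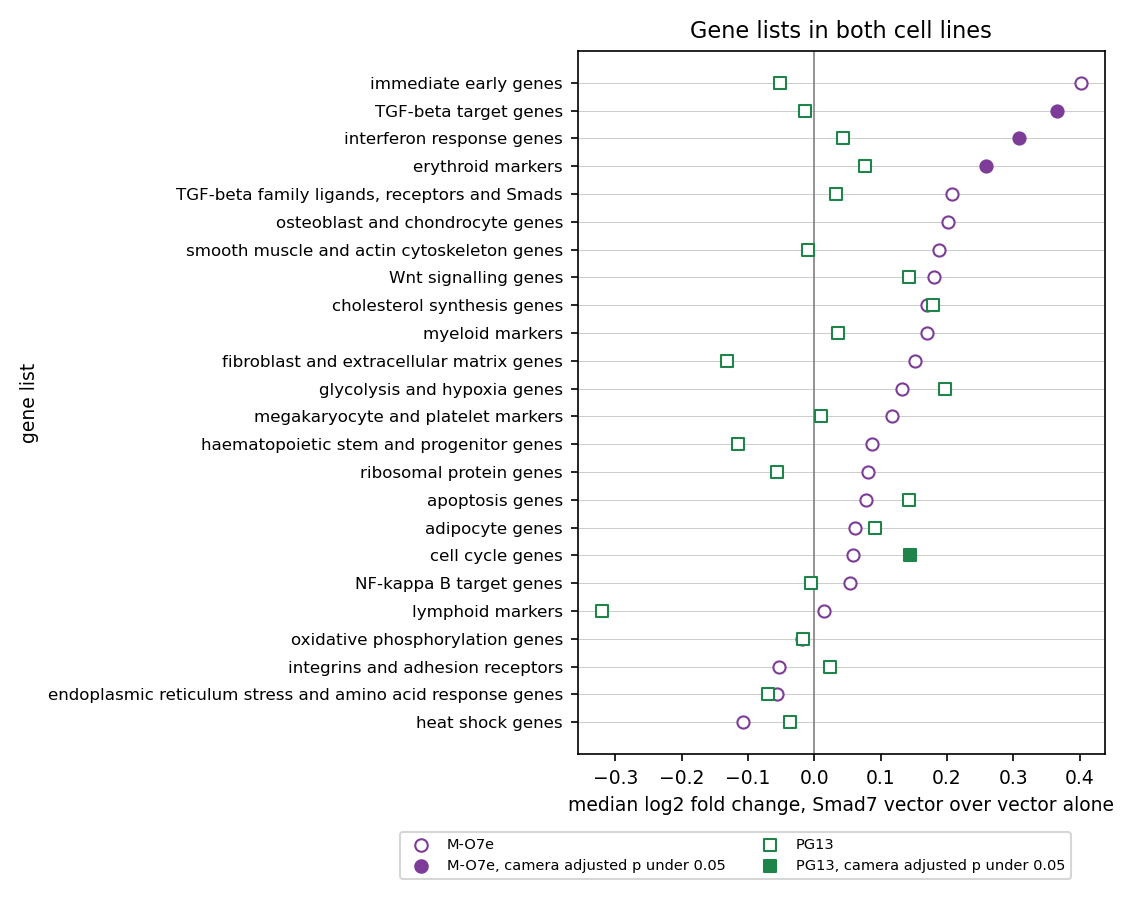
Median log2 fold change, Smad7 vector over vector alone, of the measured members of each gene list in M-O7e (circles) and PG13 (squares); filled symbols passed the camera test at an adjusted p under 0.05. TGF-beta target genes stand at 0.37 in M-O7e and -0.01 in PG13.

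In PG13 no named gene passed the test. Among 18989 probe sets 2 passed the limma test, 1 higher and 1 lower, and both are unnamed here; 922 had an unadjusted p under 0.05, where chance gives 949. Without vector replicate 2 this count was 1611, where chance gives 904, and with the ribosomal RNA signal as a covariate it was 1239. The smallest limma adjusted p of a probe set with 1 symbol was 0.227. The groups did not overlap in 10.1% of probe sets, where chance gives 10%. Genes of the fibroblast and mesenchymal lists did not pass, with log2 fold changes of 1.57 (SE 0.53) for the actin gene Acta2, -0.90 (SE 0.27) for the collagen gene Col18a1 and -0.53 (SE 0.23) for Col4a2. With the array run as a block 0 probe sets passed with limma, against 797 with an unadjusted p under 0.05. The count was 1 without Smad7 replicate 3 and without any 1 of vector replicates 1, 2 and 3.

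Cell cycle genes were the 1 list that was higher with Smad7 in PG13, with a median log2 fold change of 0.14 over 66 measured genes, 47 of them positive (camera adjusted p = 0.0210). With an estimated correlation the adjusted p was 0.659, although the estimate (0.011) lay close to the preset 0.01. None of the 66 passed alone: limma called 0 over all probe sets and 0 adjusted over the list alone, 7 had an unadjusted p under 0.05, and topoisomerase Top2a (0.51, SE 0.20, unadjusted p 0.0304 from limma) and the kinase subunit Cks1b (0.41, SE 0.16) had the smallest p. Within the shared array run the adjusted p was 0.0488. For the cell cycle genes it was 0.0942 and 0.166 without Smad7 replicates 2 and 3, and 0.0808 without vector replicate 1 and also without vector replicate 2, within a range of 0.00362 to 0.659 over all settings. Of the 10 splits of the 6 PG13 replicates into 3 and 3, 5 gave 1 list past the threshold, the real one included. A random division thus often gave as many lists. Cholesterol synthesis genes (median 0.18, Fdft1 0.62, Insig1 0.51) had a camera adjusted p of 0.0797, and glycolysis and hypoxia genes (0.20, Egln3 1.99, Hmox1 -0.40) 0.0805. TGF-beta target genes had a median of -0.01 over 32 genes (Tsc22d1 0.75, camera adjusted p = 0.931), and TGF-beta family ligands, receptors and Smads 0.03 over 33 genes (Nog -0.999, Bmpr2 -0.81, camera adjusted p = 0.898).

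Adjusted over the list alone, the ligand gene Wnt4 at -0.76 (SE 0.15, limma adjusted p = 0.742 over all probe sets) was the 1 PG13 list member lower and 0 were higher with limma. Over the 22 lists of PG13 that did not pass, 27 of 596 measured members (a gene in several lists counted in each) had an unadjusted p under 0.05. The list of Wnt4, Wnt signalling genes (median 0.14, Wnt10b 0.78), had a camera adjusted p of 0.471, as did lymphoid markers (-0.32, Cd3d -1.05), apoptosis genes (0.14, Casp8 1.34), endoplasmic reticulum stress genes (-0.07, Atf5 -0.50) and ribosomal protein genes (-0.06, Rps29 -0.41). Within the shared array run the ribosomal protein genes had a median of -0.28 and a camera adjusted p of 0.0376 at the preset correlation of 0.01. The main fit estimated a correlation of 0.241 for this list. Fibroblast and extracellular matrix genes had a median of -0.13 and a camera adjusted p of 0.228. Erythroid markers (0.08, Ank1 0.43), myeloid markers (0.04, Anpep 0.77), interferon response genes (0.04, Oasl2 1.10) and integrins and adhesion receptors (0.02, Itgb7 0.49) had 0.898. Megakaryocyte and platelet markers (0.01, Rab27b 0.94), stem and progenitor genes (-0.11, Cd34 0.85), smooth muscle and actin cytoskeleton genes (-0.01, Capg 0.53), adipocyte genes (0.09, Dgat1 -0.27), NF-kappa B target genes (-0.01, Ier3 0.53), immediate early genes (-0.05, Dusp4 0.59) and heat shock genes (-0.04, Hspa4 0.21) had 0.931, and oxidative phosphorylation genes (-0.02, Cox4i1 -0.57) 0.999. For TGF-beta target genes, smooth muscle genes, NF-kappa B target genes and immediate early genes camera gave the direction as up while the median lay below 0, as did the mean of immediate early genes (-0.05). Only 3 osteoblast and chondrocyte genes were measured (Phex 0.49, Sox9 -0.05), too few for the test.

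Whether the Smad7 effect differed between the lines was tested in the 6986 genes that both measured. TGFBR3, a coreceptor of TGF-beta, differed by 1.93 on the log2 scale (SE 0.24, limma adjusted p = 0.00636), with a log2 fold change of 2.18 in M-O7e and 0.25 in PG13, neither of which passed alone. MTCP1 differed by 3.07 (SE 0.40), CPNE5 by 1.95 (SE 0.26) and AHNAK by 3.18 (SE 0.44), higher in M-O7e. DHRSX at -2.06 (SE 0.26) and DOCK5 at -2.61 (SE 0.36) were lower in M-O7e. TGFBR3, MTCP1 and CPNE5 had not passed in M-O7e alone (limma adjusted p of 0.0602, 0.0815 and 0.0744). The fit of the difference pools the spread of both lines. A gene that varies more in M-O7e than in PG13 can therefore get a smaller SE than M-O7e alone would give. DHRSX rested on its brightest probe set: with the mean of a gene's probe sets it differed by -0.19 (limma adjusted p = 0.939). With the array run as a block AHNAK alone of these 6 passed, TGFBR3 having a limma adjusted p of 0.0826. In all, 27 genes differed, 12 with the higher and 15 with the lower change in M-O7e, and 15 of the 27 had also passed in M-O7e alone. Across the 6986 genes the log2 fold changes of the lines had a Pearson r of 0.0056 and a Spearman rho of -0.0063 (across genes, which are not independent replicates). Of 42 genes called in M-O7e and measured in both, 20 had the same sign in PG13, and 0 genes passed in both lines with limma, against 13 higher and 10 lower in both at an unadjusted p under 0.05, where independent lists give 10.7 and 11.1. The lines also differ in species and array design. The 1 Smad7 probe set of PG13 showed no rise (log2 fold change 0.02), so it is unknown whether Smad7 rose alike in both lines. The count of genes that differed was 4 with the array run as a block. It was 4, 4, 17 and 14 without M-O7e Smad7 replicates 1, 2 and 3 and vector replicate 1, 6 and 13 without PG13 Smad7 replicates 1 and 3, and 12 and 13 without PG13 vector replicates 1 and 3.

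The ribosomal RNA control probe sets varied strongly between arrays of one group. On HG-U133A their mean log2 signal was 14.80, 15.52 and 15.64 in Smad7 replicates 1 to 3 of M-O7e and 12.46, 15.81 and 12.28 in vector replicates 1 to 3. On MG_U74Av2 it was 13.18, 14.09 and 11.38 in the PG13 Smad7 replicates and 14.24, 10.49 and 14.57 in the vector replicates. None of 25 comparisons of 5 quality measures between groups had an exact permutation p under 0.2, and the smallest value adjusted over the 25 was 0.870. This test cannot go below 0.1 with 3 replicates against 3, so it cannot exclude an imbalance. In M-O7e the mean ribosomal RNA signal was 1.80 log2 units higher with Smad7 on HG-U133A and 1.68 higher on HG-U133B. With the ribosomal RNA signal as a covariate the M-O7e count was 60. The ribosomal protein genes then had a median of -0.19 (camera adjusted p = 8.67e-07 at the preset correlation), against 0.33 within the shared array run. The main fit estimated a correlation of 0.684 for this list, far above the preset one, so this p-value can be far too small. With the estimated correlation the main fit gave the list a camera adjusted p of 0.864. Neither median is therefore shown to be a shift of the list. Replicates of one group correlated at 0.801 to 0.881 in M-O7e and 0.834 to 0.888 in PG13, and replicates of different groups at 0.782 to 0.834 and 0.830 to 0.903. Vector replicate 2 gave the lowest value of both M-O7e ranges.

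**Figure D4:**
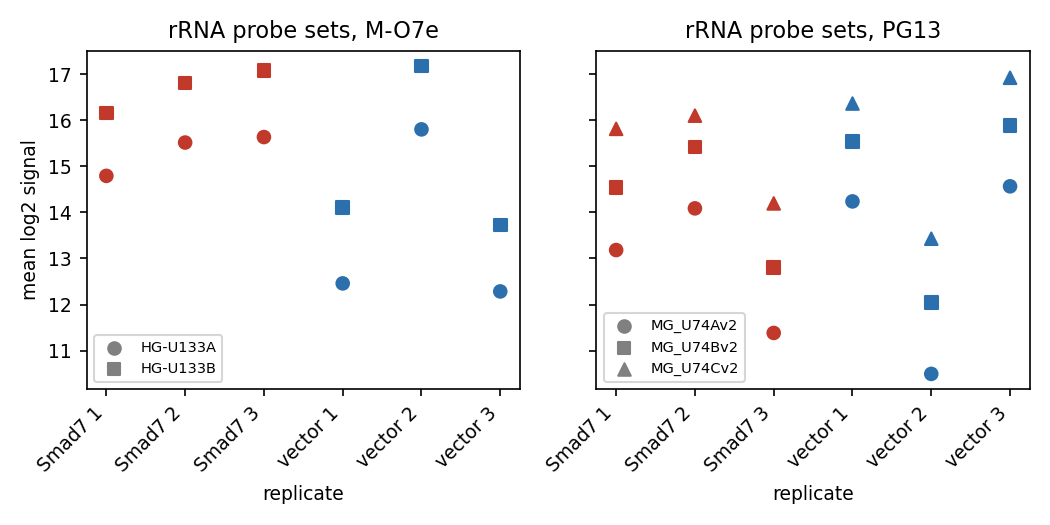
Mean log2 signal of the ribosomal RNA control probe sets on every chip of each line, 1 point per replicate and chip, with a marker for each chip. On HG-U133A, M-O7e vector replicate 2 (15.81) lies near the Smad7 replicates (14.80 to 15.64), while vector replicates 1 and 3 lie at 12.46 and 12.28.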

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

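The splits of the replicates were planned before any result was seen.

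The effect of the Smad7 vector differed between M-O7e and PG13 in 27 of 6986 genes by a test of the difference itself, although a rise of Smad7 in PG13 was not shown. The differences with the smallest p, as log2 fold change in M-O7e minus PG13, were 1.93 for TGFBR3, -2.06 for DHRSX, 3.07 for MTCP1, 1.95 for CPNE5, 3.18 for AHNAK, -2.61 for DOCK5, 1.46 for SCARB2, -2.21 for SYAP1, 2.32 for POMT2 and -1.36 for TMED4. AHNAK passed in every setting that tested it, but the 3 fits without an M-O7e Smad7 replicate did not test it. TGFBR3, MTCP1, CPNE5 and POMT2 were not tested in those fits either. The 9 genes other than AHNAK fell short with the replicate number as a block (limma adjusted p of 0.111 to 0.189) and with the array run as a block (0.0826 to 0.170). With median scaling CPNE5 (limma adjusted p = 0.108), SCARB2 (0.140), POMT2 (0.108) and TMED4 (0.0880) fell short. With the mean of a gene's probe sets DHRSX was -0.19 (limma adjusted p = 0.939), SCARB2 0.87 (0.486), TMED4 -0.85 (0.122) and POMT2 2.11 (0.108). SCARB2, SYAP1, POMT2 and TMED4 each fell short without any 1 of 3 to 6 single replicates. When the replicates of each line were split in other ways, 3 of 100 drawn splits gave as many genes, the real one included, and the highest of the others was 88. The 3 splits that gave as many all kept the real division of M-O7e, which was drawn 9 times with a median of 22 genes, while splits that divided M-O7e in another way gave at most 13. Since the real division of M-O7e is 1 of only 10, a random division of the replicates is not excluded for the M-O7e side of the differences. It is not excluded for the PG13 side either. With the real division of M-O7e, 3 of the 9 draws gave as many genes, the real one included. Exchanging the Smad7 and vector labels of PG13 gave 29 genes. The split with 88 genes put PG13 Smad7 replicates 1 and 3 with vector replicate 2 and kept the real division of M-O7e. A count several times the real one may point to a structure of the PG13 samples. With other divisions of M-O7e the same PG13 division gave 1 to 13 genes. PG13 Smad7 replicates 1 and 3 and vector replicate 2 had the lowest ribosomal RNA signal and the lowest actin 3' to 5' ratio on each of the 3 chips. They also correlated best with each other (0.888 to 0.903). This match of ranks was seen after the split, and a link of the structure to these measures was not tested.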

How the results depend on the processing

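The ribosomal RNA covariate was chosen after seeing the data, and every other alternative before. The cause of each change below was not tested. The M-O7e counts (128 changed, 43 higher, 85 lower, 103 at least 2-fold) stayed within 1.5 times at pseudocounts of 1 and 64 (127 and 136), with the values as deposited (128) and with quantile scaling (143, of which 41.3% were higher). In the same order they were 35, 7, 28 and 35 with median scaling, 264, 84, 180 and 164 with the stricter filter, 475, 164, 311 and 272 with each chip fitted on its own, and 11, 4, 7 and 11 for eBayes without trend. The array run as a block gave 2, 0, 2 and 2. No filter gave 68 changed, 39 lower and 63 at least 2-fold, the ribosomal RNA covariate 60 changed, 46 higher, 14 lower and 59 at least 2-fold (29 of the 60 shared with the 128), and the first chip alone 420 changed. Leaving out 1 replicate gave 2 to 439 changed, 0 to 166 higher, 2 to 273 lower and 2 to 282 at least 2-fold. Every call that was tested in these settings kept its sign. The 3 M-O7e lists became 0 without a filter, 5 with the stricter filter, 1 with the mean of a gene's probe sets, 0 with an estimated correlation, 5 with directional and 19 with mixed fry, and 2 to 4 without 1 replicate. SMAD7 ranged from 1.54 to 2.26 in the 3 fits without 1 replicate that tested it, and had no value under the stricter filter.

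Same-numbered replicates did not deviate together (r of -0.0017, 0.05 and 0.01 in M-O7e and -0.06, -0.20 and -0.12 in PG13), so the numbers do not pair samples. The replicate block gave 37 M-O7e calls (18 higher, 19 lower, 37 at least 2-fold), 1 PG13 call (0 lower, 1 at least 2-fold), 0 PG13 lists (cell cycle genes adjusted p = 0.0830) and 1 gene with a difference between lines.

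In PG13 the 2 calls (1 lower, 2 at least 2-fold) became 1, 0 and 1 with median scaling, for eBayes without trend and with the ribosomal RNA covariate, and 0, 0 and 0, with 0 higher, with the array run as a block. Each chip fitted on its own gave 2 lower. Leaving out 1 replicate gave 1 to 2 changed, 0 to 1 lower, 1 to 2 at least 2-fold and 0 to 2 lists. The 1 PG13 list became 3 with median scaling, 2 without a filter, with the array run as a block, with the mean of a gene's probe sets and with the ribosomal RNA covariate, 0 with an estimated correlation, and 0 with directional and 0 with mixed fry. The PG13 Smad7 value (0.02) reversed to -0.019 with quantile normalization, -0.06 without Smad7 replicate 1 and -0.19 without vector replicate 2 (-0.19 to 0.12 without 1 replicate).

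The 27 differences between lines became 10 with median scaling, 17 with the stricter filter, 4 with the array run as a block, 72 with the ribosomal RNA covariate and 4 to 40 without 1 replicate. Of the values of named genes that had passed, 241 stayed past the threshold and 221 fell short of it in M-O7e, 179 and 41 for the difference between lines, and 0 reversed. Among named genes that had not passed, these reversed: in M-O7e, with the array run as a block, SMAD2 (-0.049) and SOX6 (-0.0086); SMAD3 without Smad7 replicate 2 (0.01) and vector replicate 2 (0.13; -0.26 to 0.13 without 1 replicate); SMAD1 without Smad7 replicate 3 (0.09), vector replicate 1 (0.06) and vector replicate 3 (0.11; -0.53 to 0.11); and with the ribosomal RNA covariate SMAD5 (0.28), SMAD1 (0.56) and SMAD6 (-0.0019). In PG13 Sox9 reversed with median scaling (0.049) and without Smad7 replicate 3 (0.087) or vector replicate 2 (0.032; -0.15 to 0.087), and Smad3 without Smad7 replicate 3 (-0.20) or vector replicate 3 (-0.23; -0.23 to 0.21). Each chip fitted on its own was not run for lists or for the difference between lines, which need all chips. Signal over background was not measured, since no detection call was used. Of the 106 M-O7e calls with 1 symbol, 17 had a group under the median signal of the chip, as did SMAD7, so the size of these folds is limited by dim signals (GNG11, AHNAK, FAM241A, PPP1R12C, ENSA, SLC39A3, SLC35F3, LOC400499, RASSF4 and XRRA1 among them).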

Other observations

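The tests of the array run, of the Smad7 probe set and of sequence shared between HLA genes were chosen after the results they bear on were seen. The tests of the ribosomal RNA signal and the splits of the replicates were written before, although the covariate they use was added after the signals of the arrays were seen. The genes named in the next paragraph were chosen after their values were seen.

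In M-O7e, 9 of 18 probe sets for 6 HLA class I genes were higher with Smad7, 16 of 18 were positive and the median log2 fold change was 1.04. HLA class I genes present peptides on the cell surface. Metallothioneins, small metal-binding proteins, went the other way: 0 of 9 probe sets were positive, 2 passed as lower (MT1X -1.55, MT1H -2.05) and the median was -0.84. All 9 metallothionein probe sets carry the shared-sequence suffix. Both medians kept their sign under every scaling, but the calls were lost in several settings. With limma 0 class I probe sets passed with median scaling, without Smad7 replicate 1 or vector replicate 3, and for eBayes without trend (15 of 18 at an unadjusted p under 0.05 in each), without Smad7 replicate 2 (16) and with the array run as a block (14). Without Smad7 replicate 3 or vector replicate 1 the count was 2, and without vector replicate 2 it was 12. Of the metallothioneins 0 passed with limma without Smad7 replicate 2 or vector replicate 1 and with the array run as a block (5 of 9 at an unadjusted p under 0.05 in each), and without vector replicate 3 or for eBayes without trend (6). In the probe sets that passed, the interleukin receptor IL9R rose by 1.01, the hyaluronan receptor CD44 by 0.91 and RHAG, an erythroid membrane protein of the Rh complex, by 0.71, while the interleukin receptor chain IL2RG fell by 0.65. The chaperone CALR fell by 1.74, the cell cycle kinase CDK6 by 1.64, the transcription factor ETV6 by 1.96 and the chromatin protein HMGA1 by 2.10. The brightest probe sets of CALR (0.25) and ETV6 (0.38) did not pass and had the other sign. LTC4S, which makes leukotriene C4, rose by 1.65, and the RNA-binding ZFP36L2 by 1.32.

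The 128 M-O7e calls were set against the array run and the ribosomal RNA signal. With 10 splits of the 6 replicates a share under 0.05 cannot be had: 1 split, the real one, gave 128 calls and the highest of the others 0, and for the 3 lists 1 split gave as many and the highest other gave 1. Most of the other splits gave 1 list, so a single list past the camera threshold also arose where the groups were mixed. Vector replicate 1 was run with the Smad7 arrays, and among 131 probe sets picked without it, its median position between the Smad7 level (0) and the vector level (1) was 1.01 (quartiles 0.783 to 1.13), which argues against the array run as the whole cause. Vector replicate 2, with ribosomal RNA like that of the Smad7 arrays, lay at a median of 0.561 (quartiles 0.226 to 0.826, 438 probe sets), so part of the calls may follow the ribosomal RNA signal, and this and an effect of Smad7 cannot be told apart there. Over all tested probe sets this replicate correlated less with the Smad7 replicates (0.782 to 0.795) than vector replicates 1 and 3 did (0.801 to 0.834). With those 2 vector replicates it correlated at 0.801 and 0.802, while they correlated with each other at 0.881. Its position therefore rests on 1 replicate that was unlike every other.

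The Smad7 probe set of PG13 had a log2 fold change of 0.02. The log2 fold change in M-O7e was 2.01, and the difference between the lines had a lower 95% bound of 0.424 when the spread in both lines was counted. Within the shared array run the difference was 1.49 (SE 0.968), and the estimate minus 2 SE was -0.445, so whether spread between replicates hides a rise of that fold stays open. The criterion of this test was changed 3 times with the values known. The forms that used all replicates and set the upper 95% bound in PG13 (0.558) against the M-O7e estimate, or the difference against 0, excluded it. The forms that used the lower end of the M-O7e interval (0.54) or the shared run did not. Whether the probe set reads a part of the mRNA that the vector lacks stays open, because only 1 Smad7 probe set was on the mouse chips. Unequal expression of the vector in the lines was not tested. For the 2 PG13 calls, 10 splits are too few for a share under 0.05, and the real split was the 1 split with 2 calls (highest other 0). For the 1 list, 5 of the 10 splits gave as many, the real one included (highest other 1). A random division of the PG13 replicates therefore often gave as many lists as the real one.

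The rise of HLA class I in M-O7e may be an effect of Smad7, as a hypothesis found in the same data. With the ribosomal RNA signal as a covariate the median was 1.18 and within the shared array run 1.15, which argues against both as the cause of the median. The value within the run rests on vector replicate 1 alone. Its ribosomal RNA signal was also low (12.46 on HG-U133A, against 14.80 to 15.64 in the Smad7 replicates), so that value does not bear on the ribosomal RNA signal. Within the run 0 of the 18 passed with limma, 14 had an unadjusted p under 0.05, and the median SE was 0.227 against 0.158. Sequence shared between the genes stays open: the 16 probe sets with the shared-sequence suffix had a median of 1.10 and the 2 without it -0.29, and 1 of these 2 lay below the level set for it by more than its error. The rise therefore cannot be told apart from that of fewer genes read by many probe sets.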
